A study of Mus musculus with 70 samples.

How the data were processed

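The labels describe 70 Affymetrix mouse genome arrays of right lung lobe RNA from female B6C3F1 mice exposed for 13 weeks, on 7 days a week in feed or on 5 days a week by gavage at 5 ml/kg. Total RNA was extracted with Trizol and RNeasy and labelled with biotin, per the labels. The deposited values were read as log2 probe set signals, and they lie on nearly the same scale in all arrays. The method of summarization and normalization is not given in the sources used here. The log2 scale was read from the deposited values, which run from 2.47 to 14.5 with no missing value, and whose array medians lie between 5.41 and 5.52. The highest correlation of 2 arrays was 0.997, and 0 pairs were identical.

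Probe sets were named from the platform table, with symbols looked up by Entrez identifier in the RefSeq gene table of assembly GRCm38.p6 for 18032 symbols. Of 45101 probe sets, 64 control probe sets were left out. Of the rest 34945 had 1 gene symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol entered the comparisons, and each gene was represented by the probe set with the highest mean over all arrays. Other probe sets of a gene were left to an alternative that averages them. Genes whose probe set mean lay above the 30th percentile (4.25 on the log2 scale) were kept, which left 14593 genes of 18193.

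Groups were taken from the chemical, vehicle and animal identifier in the labels. The number before the hyphen in the identifier defines set 1 and set 2, and its meaning is not given in the sources used here. Control groups were kept apart by set and vehicle, which gave 18 groups. One model with a mean per group was fitted to all 70 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8), so that all groups share the estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Errors of log2 changes are standard errors of that fit, and intervals are 95% intervals. Counts expected by chance are 5% of the genes tested. The number of arrays limits the precision.

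In all, 40 gene lists fixed in advance were tested with camera at its preset correlation of 0.01, adjusted over all 40 lists and 13 chemicals. For direct contrasts and for tumour class the adjustment ran over the lists. Each camera p is given beside the p with an estimated correlation. Members were also tested with the gene p-values adjusted over the list alone. Tumour class was tested with limma on 13 columns, 1 per chemical (treated mean minus matched control mean), 7 against 6. Classification left out 1 chemical at a time, chose 50 genes on the other 12, and scored the animals left out with a diagonal linear discriminant. It was compared with 100 permutations of the class labels. Overlaps between chemicals are given only for pairs with different controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

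The comparisons, their tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, apart from the alternatives and tests that the closing section names as chosen later. The rule named, for each chemical, up to 8 genes with the largest rise and up to 8 with the largest fall among called genes whose treated animals all lay beyond all matched controls. It added up to 4 called members of each called list. For direct contrasts of treated groups it named up to 12 genes in each direction, for control groups up to 5, and for tumour class, where none passed, the 5 with the smallest p in each direction. The text gives a selection of these, and genes it names without a call were singled out after their values were seen and are given as not passing.

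Alternatives were: no filter and a filter at the 50th percentile, the mean over all probe sets of a gene, quantile normalization over again, only the arrays of the 2 groups compared, a variance trend with robust estimation, array weights, each array left out in turn, controls of both sets pooled, and the amount of RNA solution handed to the array core as a block. For lists they were an estimated correlation, fry, and lists without genes that another list holds. For tumour class they were no subtraction of controls, animals as replicates with and without the chemical as a random block, feed chemicals alone, and route and vehicle as a block. Covariates for RNA integrity and for the axis along which animals of 1 group differ, and the fit without arrays that stand apart, were added later.

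The scripts' statistics were tested on simulated data with 200 genes changed. In the simulated comparison of 1,5-naphthalenediamine, 58.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered among 14593 genes. For coumarin, with 4 against 8 arrays, the shares were 76.1%, 95.5% and 100%. The simulated noise was independent between genes, which the real values are not. RNA integrity numbers in the labels cover part of the animals (0 of 4 with diazinon) and were not used in a fit.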

Results

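Gene expression was measured in the right lung lobe of 70 female B6C3F1 mice on Affymetrix mouse genome arrays, 1 array per animal, after 13 weeks of exposure. The labels name 13 chemicals and class 7 of them as positive and 6 as negative for lung tumours. Feed carried 1,5-naphthalenediamine at 2000 ppm and 2,2-bis(bromomethyl)-1,3-propanediol at 1250 ppm among the positive chemicals. It carried N-(1-naphthyl)ethylenediamine dihydrochloride at 2000 ppm, pentachloronitrobenzene at 8187 ppm, 4-nitroanthranilic acid at 10000 ppm, diazinon at 200 ppm and malathion at 16000 ppm among the negative ones. Corn oil gavage carried 2,3-benzofuran at 240 mg/kg, 1,2-dibromoethane at 62 mg/kg, coumarin at 200 mg/kg and benzene at 100 mg/kg, all positive. Water gavage carried N-methylolacrylamide at 50 mg/kg, which is positive, and 2-chloromethylpyridine hydrochloride at 250 mg/kg, which is negative. The animal identifiers fall into set 1 and set 2. In set 1 every group held 3 mice: 1,5-naphthalenediamine, N-(1-naphthyl)ethylenediamine dihydrochloride, pentachloronitrobenzene and feed controls, and 2,3-benzofuran and corn oil controls. In set 2 every treated group held 4 mice, with 4 feed controls, 4 water controls and 8 corn oil controls. Each chemical was set against the controls of its own set and vehicle. The number of arrays limits the precision of every value.

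The largest differences between arrays followed the set. The first principal component held 55.1% of the variance, and its group means ran from -51.4 to -43 in set 1 and from 0.00950 to 46.1 in set 2. Within set 2 the 4 water controls had the highest mean, 46.1 (SD 15.4), against 13.8 (SD 21.9, n = 8) in the corn oil controls and 4.76 (SD 14.2, n = 4) in the feed controls. The mean 3' minus 5' difference of the Actb and Gapdh control probe sets, a sign of RNA integrity, ran from 0.12 log2 units in the water controls to 0.39 with 1,2-dibromoethane, where animal 2-56 stood at 0.989 and the others at 0.135 to 0.254.

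**Figure D1:**
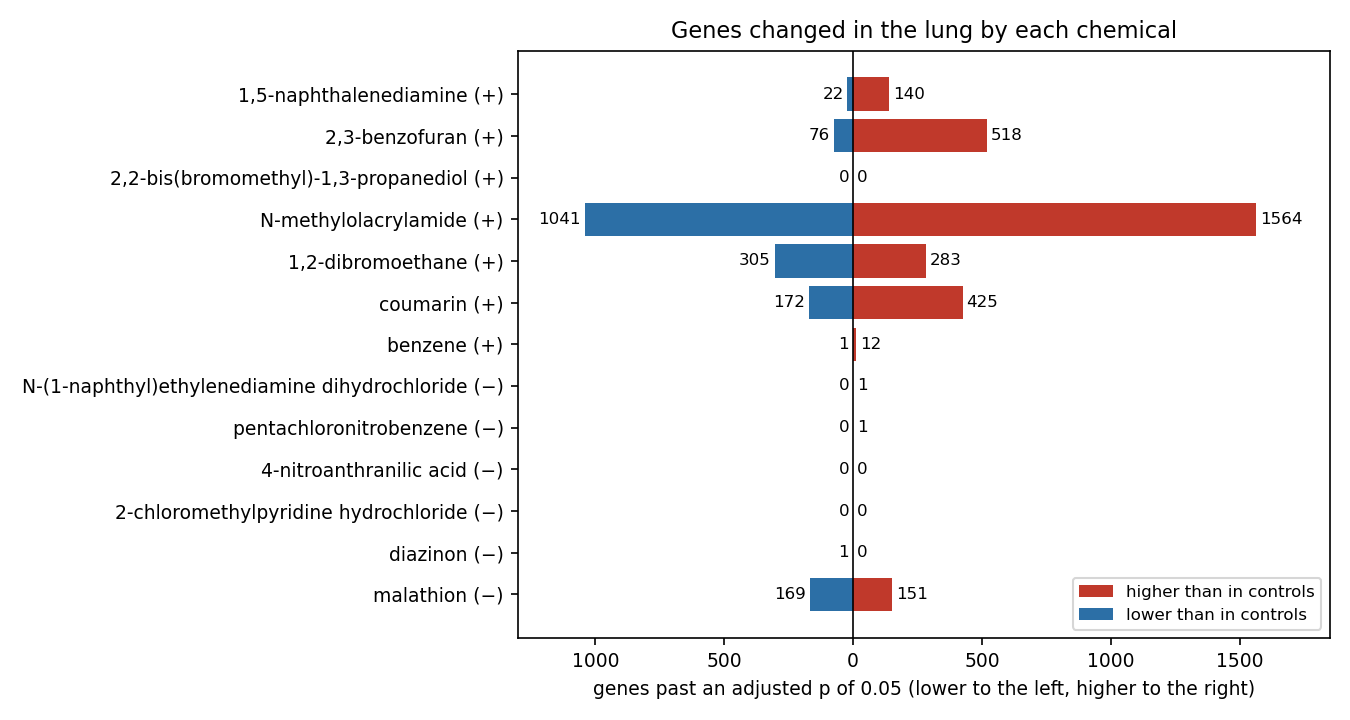
Number of genes higher or lower than in the matched controls at an adjusted p under 0.05 (limma, 14593 genes tested), for each of the 13 chemicals. The counts run from 0 to 2605.

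1,5-Naphthalenediamine raised enzymes of xenobiotic metabolism and of the oxidative stress response (3 treated against 3 feed control mice). Cyp1a1, a monooxygenase that the aryl hydrocarbon receptor (AhR) induces, rose by 6.05 ± 0.42 (SE) log2 units, from 5.68 (SD 0.88) to 11.73 (SD 0.25; limma adjusted p = 1.88e-16). Ces1g, a carboxylesterase, rose by 4.57 ± 0.37 (adjusted p = 3.33e-14), and Nqo1, a quinone reductase, by 3.14 ± 0.31 (adjusted p = 2.03e-11). The glutathione enzymes Gpx2 and Gsta2 rose by 2.46 ± 0.25 and 2.08 ± 0.21. Of the 34 measured genes on the list of NRF2 and glutathione genes, 23 rose and 0 fell (31 rose when adjusted over the list alone), with a mean change of 0.92 (camera adjusted p = 7.57e-91, and 1.51e-07 with an estimated correlation). Of 7 AhR target genes 4 rose, also 4 when adjusted over the list alone, among them Cyp1b1 by 1.73 ± 0.30 and Aldh3a1 by 1.78 ± 0.25 (camera adjusted p = 1.15e-17, and 1.51e-07 with an estimated correlation). Of 24 phase I enzymes 9 rose and 0 fell (11 rose and 2 fell when adjusted over the list alone), with camera adjusted p = 1.7e-14, and 0.00168 with an estimated correlation. Without the genes that other lists also hold the phase I enzymes were not called (camera adjusted p = 0.185).

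Immunoglobulin and plasma cell genes were also higher with 1,5-naphthalenediamine. Igkv6-14 rose by 3.38 ± 0.56 (adjusted p = 4.65e-05), Igk by 3.50 ± 0.66 (adjusted p = 0.000483), and Mzb1, a chaperone of antibody-secreting cells, by 1.97 ± 0.29 (adjusted p = 2.05e-06). Ighm rose by 3.84 ± 0.88 (adjusted p = 0.00827) and Jchain by 3.61 ± 0.73 (adjusted p = 0.00153). Of 20 B cell and plasma cell markers 4 rose, also 4 when adjusted over the list alone, with a mean change of 0.75 and a median of 0.14 (camera adjusted p = 2.21e-05, and 0.462 with an estimated correlation). Ms4a1 (0.14), Cd79a (0.35), Cd79b (-0.05) and Cd22 (0.02) did not pass. Erythroid (mean change 0.44) and ciliated cell markers (0.17) were also called higher, and endothelial (-0.24), alveolar type I (-0.15) and T and NK cell markers (-0.28) lower. In each 0 or 1 member passed, and 0 to 4 when adjusted over the list alone (camera adjusted p from 7.59e-05 to 0.0034, and from 0.344 to 0.796 with an estimated correlation). Gp2, a membrane glycoprotein, rose by 4.30 ± 0.45 and Cd177, a neutrophil surface protein, by 3.39 ± 0.55. The largest falls were those of Chad, a cartilage matrix protein (-1.65 ± 0.30, adjusted p = 0.00024), Lrrc26 (-1.42 ± 0.18) and Slc4a5, a bicarbonate transporter (-1.38 ± 0.18). In all, 162 of 14593 genes passed, 140 higher and 22 lower. Without feed control 1-29 the count was 80 and without treated animal 1-4 it was 103. The calls of Ighm in 1,5-naphthalenediamine (adjusted p = 0.0973) and Jchain in 1,5-naphthalenediamine (adjusted p = 0.0675) ended without control 1-29, and that of Ighm also without treated animal 1-2 (adjusted p = 0.0816).

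N-(1-Naphthyl)ethylenediamine dihydrochloride and pentachloronitrobenzene, negative chemicals given in feed in the same set, each changed Cyp1a1 and no other gene at the threshold (3 treated against 3 feed control mice). Cyp1a1 rose by 3.17 ± 0.42 with N-(1-naphthyl)ethylenediamine dihydrochloride, to 8.84 (SD 0.20; adjusted p = 5.78e-06). With pentachloronitrobenzene it rose by 3.58 ± 0.42, to 9.25 (SD 0.47; adjusted p = 1.43e-07). Unadjusted p lay under 0.05 for 1103 and 429 genes (729.65 expected by chance). Ces1g changed by 0.44 and 0.76 log2 units and did not pass. The 7 AhR target genes had a mean change of 0.71 with pentachloronitrobenzene (camera adjusted p = 1.57e-05, and 0.0131 with an estimated correlation) and of 0.49 with N-(1-naphthyl)ethylenediamine dihydrochloride (camera adjusted p = 0.0495, and 0.436 with an estimated correlation). In each case 1 member, Cyp1a1, rose, and also 1 when adjusted over the list alone. Without treated animal 1-14 the count for N-(1-naphthyl)ethylenediamine dihydrochloride was 9, and with only the arrays of the 2 groups it was 4. Array weights gave 708 genes for N-(1-naphthyl)ethylenediamine dihydrochloride and 75 for pentachloronitrobenzene. Controls of both sets pooled gave 1637 and 1015, but these counts carry the difference between the sets (6052 genes between their feed controls).

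1,5-Naphthalenediamine and N-(1-naphthyl)ethylenediamine dihydrochloride share a naphthalene ring with amino substituents and were fed at the same 2000 ppm, so that their lungs were also compared directly (3 against 3 mice). Cyp1a1 was higher with 1,5-naphthalenediamine by 2.88 ± 0.42 (95% interval 2.04 to 3.72, adjusted p = 2.03e-06). Ces1g was higher by 4.13 ± 0.37 (adjusted p = 1.63e-12), and of the genes added after the single comparisons were seen, Nqo1 by 2.77 (95% interval 2.16 to 3.38, adjusted p = 9.98e-10) and Gpx2 by 2.36 (95% interval 1.86 to 2.85). Sncg, a synuclein, was higher by 2.80 ± 0.19 (adjusted p = 2.54e-17), Ighm by 4.02 ± 0.88 and Jchain by 3.75 ± 0.73. Lower with 1,5-naphthalenediamine were Lrrc26 (-1.35 ± 0.18) and Slc4a5 (-1.19 ± 0.18). Of the 34 NRF2 and glutathione genes 25 were higher and 30 when adjusted over the list alone (camera adjusted p = 8.62e-86, and 6.09e-08 with an estimated correlation). The clock genes in phase with Dbp had a mean difference of -0.86, 1 of 13 lower and 7 when adjusted over the list alone (camera adjusted p = 3e-09, and 0.0364 with an estimated correlation). The contrast called 243 genes, 217 higher and 26 lower with 1,5-naphthalenediamine, and 158 without 1,5-naphthalenediamine animal 1-5.

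2,3-Benzofuran raised many of the same kinds of enzyme (3 treated against 3 corn oil control mice of set 1). Ces1g rose by 3.36 ± 0.37, from 5.00 to 8.36 (adjusted p = 1.34e-08). Nqo1 rose by 2.11 ± 0.31 (adjusted p = 7.58e-06), Acsm1, an acyl-CoA synthetase, by 1.83 ± 0.28, Gpx2 by 1.68 ± 0.25 and Aldh3a1, an aldehyde dehydrogenase, by 1.56 ± 0.25. Of 34 NRF2 and glutathione genes 22 rose and 0 fell (28 rose when adjusted over the list alone), with a mean change of 0.65 (camera adjusted p = 1.6e-31, and 0.00388 with an estimated correlation); Gsta2 rose by 1.48 ± 0.21 and Mgst2 by 1.25 ± 0.21. Of 25 ciliated cell markers 6 rose (11 when adjusted over the list alone), among them Cfap126 by 0.94 ± 0.17 (camera adjusted p = 2.16e-06, and 0.53 with an estimated correlation). Alveolar type I cell markers fell in 2 of 15 cases and in 3 when adjusted over the list alone (camera adjusted p = 1e-04, and 0.388 with an estimated correlation). Alveolar type II, endothelial, fibroblast and neutrophil markers were also called lower, with 0 or 1 member passing and 0 to 2 when adjusted over the list alone (camera adjusted p from 0.000284 to 0.0351, and from 0.352 to 0.853 with an estimated correlation). Of 29 matrix genes 8 fell (10 when adjusted over the list alone), among them Col1a1, a collagen chain, by -1.05 ± 0.27 (camera adjusted p = 1.39e-12, and 0.159 with an estimated correlation). In all 594 genes passed, 518 higher and 76 lower, and 9 with only the arrays of the 2 groups. Without treated animal 1-10 the count was 47, without 1-6 it was 918, without 1-8 it was 1331, without control 1-22 it was 129 and without control 1-24 it was 299. Animal 1-10 had a 3' minus 5' value of 0.523, against 0.161 in 1-6 and 0.102 in 1-8. Cfap126 in 2,3-benzofuran (adjusted p = 0.0655) and Col1a1 in 2,3-benzofuran (adjusted p = 0.573) no longer passed without treated animal 1-10, and Col1a1 also not without control 1-22 (adjusted p = 0.0628) or 1-24 (adjusted p = 0.0958).

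Coumarin raised Ces1g, Pnliprp1 and NRF2 and glutathione genes (4 treated against 8 corn oil control mice of set 2). Ces1g rose by 3.59 ± 0.28, from 5.56 (SD 0.42) to 9.15 (SD 0.65; adjusted p = 8.28e-15). Pnliprp1, a pancreatic-type lipase, rose by 2.37 ± 0.17 (adjusted p = 6.78e-16), Acsm1 by 2.42 ± 0.21 (adjusted p = 7.38e-13), Agr2, a disulfide isomerase of mucus-secreting cells, by 2.64 ± 0.35 and Nqo1 by 2.19 ± 0.23 (adjusted p = 2.64e-10). Of 34 NRF2 and glutathione genes 20 rose and 0 fell (22 rose when adjusted over the list alone), among them Gpx2 by 1.50 ± 0.19 and Cbr1, a carbonyl reductase, by 1.03 ± 0.08 (camera adjusted p = 1.6e-31, and 0.00388 with an estimated correlation). Of 24 phase I enzymes 10 rose (14 rose and 1 fell when adjusted over the list alone), among them Ces1f by 1.65 ± 0.21 and Adh7 by 1.45 ± 0.19 (camera adjusted p = 1.95e-16, and 0.00074 with an estimated correlation). Of 23 serine esterase and hydrolase genes 6 rose, and 7 rose and 3 fell when adjusted over the list alone, with camera adjusted p = 0.00522, which was 0.413 with an estimated correlation and 0.447 without genes that another list holds. In all 597 genes passed, 425 higher and 172 lower, and 146 with only the arrays of the 2 groups.

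Markers of several cell types moved with coumarin as well. Ciliated cell markers rose in 6 of 25 cases and in 13 when adjusted over the list alone, led by Cfap126 (0.81 ± 0.13, adjusted p = 1.05e-05) and Rsph1 (0.74 ± 0.13), with camera adjusted p = 1.04e-07, and 0.462 with an estimated correlation. Among 14 club cell markers 6 rose and 8 when adjusted over the list alone, such as Aldh1a7 (0.51 ± 0.12), with a mean change of 0.77 (camera adjusted p = 8.83e-07, and 0.342 with an estimated correlation). Endothelial markers fell in 5 cases and in 8 when adjusted over the list alone, with Cdh5, the cadherin of vascular junctions, at -0.57 ± 0.11 (adjusted p = 0.000636; camera adjusted p = 4.35e-07, and 0.11 with an estimated correlation). Of 26 T cell and NK cell markers 9 fell and 10 when adjusted over the list alone, with a mean change of -0.32 (camera adjusted p = 2.41e-06, and 0.462 with an estimated correlation). Other falls were those of Gprin3 (-1.74 ± 0.25, adjusted p = 1.35e-06), the noncoding RNA Malat1 (-1.26 ± 0.23) and Eln, elastin (-1.02 ± 0.23, adjusted p = 0.00262). Clock genes in phase with Dbp had a mean change of 0.61, with 4 of 13 risen and 9 when adjusted over the list alone, among them Per3 by 1.19 ± 0.29 (camera adjusted p = 2.21e-05, and 0.344 with an estimated correlation).

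1,2-Dibromoethane raised the carboxylesterases Ces1g and Ces1f and lowered Eln and Npr1 (4 treated against 8 corn oil control mice). Ces1g rose by 2.13 ± 0.28 (adjusted p = 9.07e-07), Ces1f by 1.82 ± 0.21 (adjusted p = 6.61e-08), Pnliprp1 by 1.45 ± 0.17 and Gpx2 by 0.99 ± 0.19 (adjusted p = 0.000918). Eln fell by 1.35 ± 0.23 on the log2 scale (adjusted p = 0.00015) and Npr1, the receptor of atrial natriuretic peptide, by 0.94 ± 0.15, from 6.80 to 5.86. The list of 23 serine esterase and hydrolase genes was not called (2 rose, and 4 rose and 1 fell when adjusted over the list alone, with camera adjusted p = 0.688, and 0.955 with an estimated correlation). Siglecf, a surface protein of alveolar macrophages and eosinophils, fell by 1.07 ± 0.21 (adjusted p = 0.00142). Of 25 ciliated cell markers 8 rose (16 when adjusted over the list alone), among them Dynlrb2 by 0.73 ± 0.14 (camera adjusted p = 2.14e-13, and 0.344 with an estimated correlation). Of 34 NRF2 and glutathione genes 12 rose (16 when adjusted over the list alone), with a mean change of 0.29 (camera adjusted p = 2.14e-13, and 0.185 with an estimated correlation). Of 29 matrix genes 6 fell (10 when adjusted over the list alone), with camera adjusted p = 6.81e-06, and 0.436 with an estimated correlation. In all 588 genes passed, 283 higher and 305 lower, with 360 without treated animal 2-54 and 351 without 2-58. With only the arrays of the 2 groups 10 passed, and more genes were higher than lower with quantile normalization over again (317 and 211). The same held with controls of both sets pooled (347 and 102), which brings in the difference between the sets. The 3' minus 5' value averaged 0.386 in the treated animals and 0.217 in their controls (exact permutation p = 0.273), and the higher mean rested on treated animal 2-56 (0.989, the others 0.135 to 0.254). With that value as a covariate 652 genes passed, and 442 of these were among the 588.

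Benzene changed 13 genes, 12 higher and 1 lower (4 treated against 8 corn oil control mice; 1382 genes had an unadjusted p under 0.05). Ephx1, the microsomal epoxide hydrolase, rose by 0.66 ± 0.07, from 11.06 to 11.72 (adjusted p = 4.54e-08). Dglucy, a glutamate cyclase, rose by 0.79 ± 0.11 (adjusted p = 7.29e-06), and the carboxylesterases Ces1f and Ces2e by 1.18 ± 0.21 (adjusted p = 0.00189) and 0.64 ± 0.11 (adjusted p = 0.00175). Of 29 p53 target genes 4 rose and 6 when adjusted over the list alone, with a mean change of 0.15 (camera adjusted p = 0.000839, and 0.149 with an estimated correlation). They were Ephx1, Phlda3 (0.69 ± 0.12, adjusted p = 0.00175), Ddit4l (0.61 ± 0.13) and Zmat3 (0.49 ± 0.11, adjusted p = 0.0404). The call of Phlda3 in benzene ended without treated animal 2-90 (adjusted p = 0.0925). That of Zmat3 in benzene ended without corn oil control 2-132, 2-134, 2-60, 2-95 or 2-99 or treated animal 2-82, 2-86 or 2-90 (adjusted p from 0.0609 to 0.335), and that of Ddit4l in benzene without control 2-134 or 2-60 or treated animal 2-82, 2-85 or 2-90 (adjusted p from 0.054 to 0.304). With only the arrays of the 2 groups the count was 0. It was 6 without control 2-134 or 2-60, 7 without treated animal 2-85, 6 without 2-86 and 5 without 2-90. Markers of cardiac muscle (mean change -0.56), cartilage (-0.21), squamous epithelium (-0.16), skeletal muscle (-0.13) and T and NK cells (-0.13) were also called lower with benzene. Those of mesothelium (0.38) and platelets (0.19) were called higher. For these lists camera adjusted p ran from 1.02e-07 to 0.0449, and from 0.4 to 0.842 with an estimated correlation.

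N-Methylolacrylamide differed from the water controls in 2605 genes, 1564 higher and 1041 lower (4 against 4 mice). Plagl1, a zinc finger transcription factor, was higher by 1.90 ± 0.35 (8.32 to 10.22, adjusted p = 0.00147), Cdh11, a cadherin of mesenchymal cells, by 1.58 ± 0.28 (adjusted p = 0.00132) and Lysmd3 by 1.92 ± 0.38 (adjusted p = 0.00194). Adamts15, a matrix protease, was lower (-1.14 ± 0.26, adjusted p = 0.00364), as were Rbfox3 (-0.95 ± 0.22) and Rasd1 (-0.91 ± 0.22). Of 21 glucocorticoid target genes 6 were lower and 9 when adjusted over the list alone (camera adjusted p = 0.000735, and 0.548 with an estimated correlation). Among the heat shock genes 5 were higher and 6 when adjusted over the list alone, led by Dnajb4 (1.42 ± 0.30; camera adjusted p = 0.0449, and 0.834 with an estimated correlation). The same animals differed from the feed controls of set 2 in 127 genes and from the corn oil controls of set 2 in 4. The count against the water controls was 1435 without control 2-121, 299 without 2-124, 3979 without 2-129 (1939 higher and 2040 lower), 909 without treated animal 2-102 and 1098 without 2-106. With only the arrays of the 2 groups it was 1338. With the score of each array on an axis of variation taken from the other groups as a covariate it was 1.

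2-Chloromethylpyridine hydrochloride, the negative chemical in water, changed 0 genes at an adjusted p under 0.05 in limma (4 against 4 mice; 1710 at an unadjusted p under 0.05, smallest adjusted p 0.351), 1 without water control 2-129 and 314 with array weights. The B cell and plasma cell markers had a mean change of 0.50 with 0 members passing, also 0 when adjusted over the list alone (camera adjusted p = 6.8e-07, and 0.388 with an estimated correlation). The glucocorticoid target genes had a mean change of -0.46 with 5 members passing when adjusted over the list alone (camera adjusted p = 9.03e-07, and 0.352 with an estimated correlation). Ces1g changed by 1.15 and did not pass (adjusted p = 0.351). Set against the feed controls these animals differed in 2484 genes, and against the corn oil controls in 135.

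Heat shock and endoplasmic reticulum chaperones were lower with malathion than in its feed controls of set 2 (4 against 4 mice). Part of the difference may lie in these controls. Hsph1 fell by 2.25 ± 0.38 on the log2 scale, from 10.96 to 8.71 (adjusted p = 0.000348). Of 18 heat shock genes 9 fell and 12 when adjusted over the list alone, with a mean change of -0.95 (camera adjusted p = 9.01e-14, and 0.11 with an estimated correlation). Of 26 endoplasmic reticulum stress genes 6 fell and 11 when adjusted over the list alone, among them Hspa5, the main luminal chaperone, by 0.75 ± 0.15 (adjusted p = 0.00195) and Ddit3 by 0.83 ± 0.17 (adjusted p = 0.0042; camera adjusted p = 1.24e-06, and 0.248 with an estimated correlation). Cirbp, a cold-induced RNA-binding protein, rose by 2.10 ± 0.36, from 7.10 to 9.20 (adjusted p = 0.000374), and Psrc1, a microtubule regulator and p53 target, by 1.90 ± 0.27 (adjusted p = 1.49e-05). Gpx2 rose by 1.13 ± 0.21 (adjusted p = 0.0012) and Ces1g by 1.73 ± 0.32 (adjusted p = 0.000846). Of 34 NRF2 and glutathione genes 6 rose and 1 fell (10 and 2 when adjusted over the list alone; camera adjusted p = 0.000316, and 0.584 with an estimated correlation). Iyd, an iodotyrosine deiodinase, fell by 1.82 ± 0.24 (adjusted p = 4.27e-06), and Cyp2c29, a monooxygenase, by 2.62 ± 0.57 (adjusted p = 0.0059).

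Malathion changed 320 genes in all, 151 higher and 169 lower, and 178 (82 higher, 96 lower) with the amount of RNA solution handed to the array core as a block. The count was 125 without feed control 2-42, 178 without 2-44, 182 without 2-45, 142 without malathion animal 2-38 and 77 without 2-39. Diazinon, the other organophosphate, changed 1 gene, Cyp2c29, which fell by 2.98 ± 0.57 (adjusted p = 0.0323; 714 genes at an unadjusted p under 0.05; 4 against 4 mice). Its treated and control animals overlapped, and it was singled out after its values were seen. Cyp2c29 was higher in these feed controls (8.13) than in any other group, the other feed chemicals of set 2 included. The count for diazinon was 0 with the amount handed to the core as a block and with only the arrays of the 2 groups. It was also 0 without feed control 2-42, 2-43 or 2-45 or diazinon animal 2-24, 2-25 or 2-28, and 2 without control 2-44. Cell cycle genes had a mean change of 0.30 with diazinon, 2 passing when adjusted over the list alone (camera adjusted p = 1.49e-13, and 0.344 with an estimated correlation). Markers of B cells (mean change 0.39), T cells and NK cells (0.17), erythroid cells (0.24), interstitial macrophages (0.14) and alveolar type II cells (0.05) were also called higher with diazinon, and those of ciliated cells (-0.22) and cardiac muscle (-0.49) lower. In each of these 0 members passed, also 0 when adjusted over the list alone (camera adjusted p from 6.68e-05 to 0.0495, and from 0.5 to 0.812 with an estimated correlation). Array weights gave 273 genes for diazinon and 2371 for malathion.

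Diazinon and malathion are both organophosphate insecticides, and were fed at different doses, 200 and 16000 ppm. Compared directly (4 against 4 mice), 41 genes differed, 16 higher and 25 lower with diazinon. Psrc1 was lower with diazinon (-1.71 ± 0.27, 95% interval -2.25 to -1.18, adjusted p = 0.000193), as were Upk3a, a urothelial plaque protein (-1.51 ± 0.24, adjusted p = 0.000193), and Gpx2 (-1.26 ± 0.21, adjusted p = 0.000735). Iyd was higher with diazinon by 1.54 ± 0.24 (adjusted p = 0.000193) and Slc4a5 by 0.88 ± 0.15. The p53 target genes had a mean difference of -0.24, 1 of 29 lower and 5 when adjusted over the list alone (camera adjusted p = 3.1e-07, and 0.00278 with an estimated correlation). The club cell markers were called higher with diazinon (camera adjusted p = 0.000247, and 0.339 with an estimated correlation), 2 of 14 passing and 4 when adjusted over the list alone, with a median difference of 0.07 and a mean of -0.10. With only the arrays of the 2 groups the count was 0. It was 142 without malathion animal 2-33, 10 without 2-38, 6 without 2-39 and 20 without diazinon animal 2-25.

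2,2-Bis(bromomethyl)-1,3-propanediol changed 0 genes at an adjusted p under 0.05 in limma (4 treated against 4 feed control mice; 1568 at an unadjusted p under 0.05), and 8 without treated animal 2-2. The count was 88 with only the arrays of the 2 groups (61 higher, 27 lower) and 2958 with array weights (1504 higher, 1454 lower). It was 4049 with controls of both sets pooled, which brings in the difference between the sets. Cirbp (1.69 ± 0.36) and Psrc1 (1.34 ± 0.27) were among the genes with the smallest adjusted p, 0.0633, which did not pass. The heat shock genes had a mean change of -0.49, 11 of them lower when adjusted over the list alone (camera adjusted p = 3.55e-07, and 0.354 with an estimated correlation). Markers of B cells (mean change 0.50), T and NK cells (0.30) and neutrophils (0.57) were called higher, and those of ciliated cells (-0.30) lower. In each 0 members passed, and 0 to 4 when adjusted over the list alone (camera adjusted p from 1.23e-06 to 0.00425, and from 0.441 to 0.783 with an estimated correlation). 4-Nitroanthranilic acid also changed 0 genes in limma (4 against 4 mice; 272 at an unadjusted p under 0.05), against 313 with array weights. Cyp1a1 had its smallest adjusted p, 0.122, with a change of 1.78 ± 0.36. The 7 AhR target genes had a mean change of 0.37, 2 of them passing when adjusted over the list alone (camera adjusted p = 0.000506, and 0.11 with an estimated correlation).

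**Figure D2:**
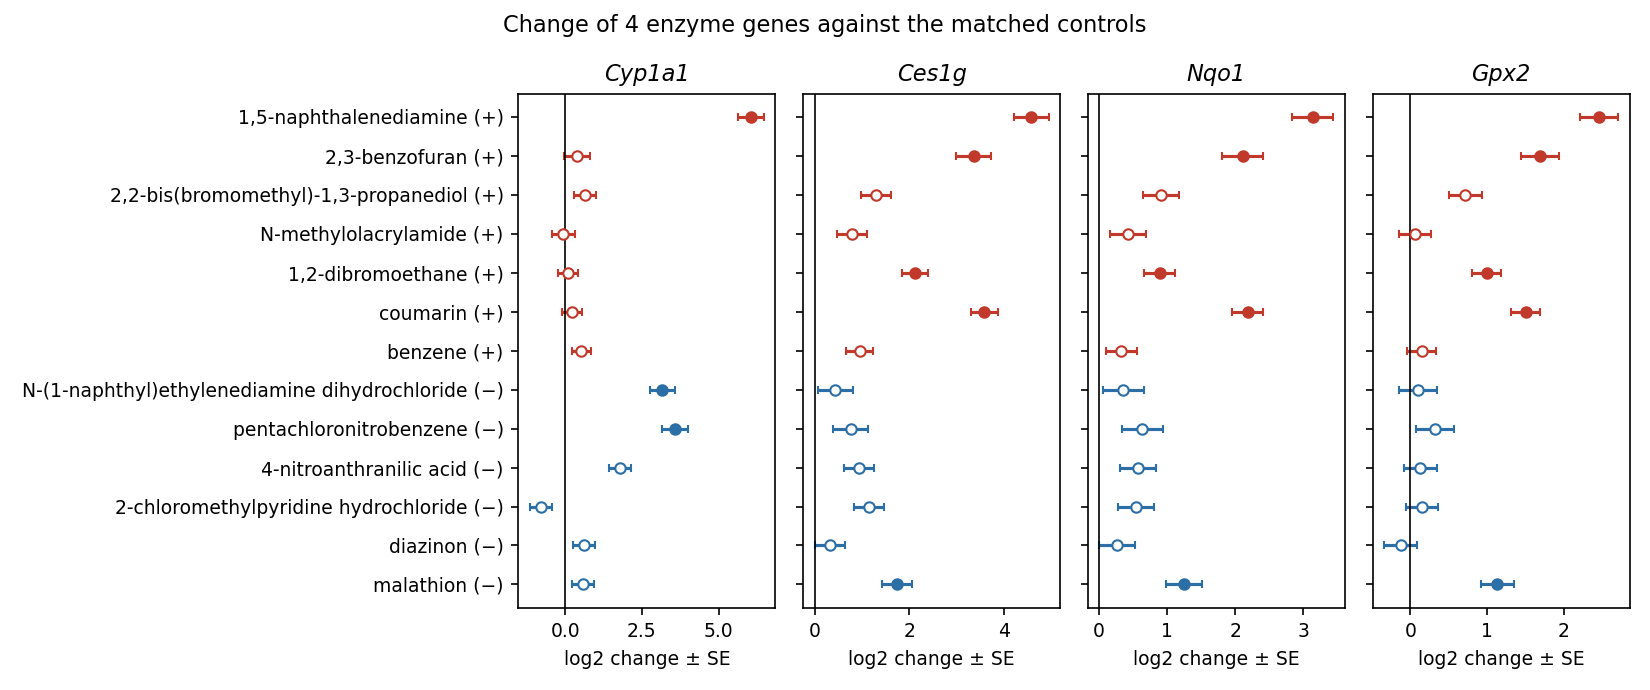
Log2 change (with SE) of Cyp1a1, Ces1g, Nqo1 and Gpx2 against the matched controls for the 13 chemicals; red marks positive and blue negative chemicals, filled points have a limma adjusted p under 0.05 and open points do not. Cyp1a1 reached 6.05 with 1,5-naphthalenediamine, and Ces1g reached 4.57.

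Genes called higher were shared between chemicals whose controls were different animals. 2,3-Benzofuran and coumarin both raised 150 genes, against 15.1 for independent lists, among them Ces1g, Nqo1, Acsm1, Aldh3a1, Fetub, Gpx2 and Ces1f. 1,5-Naphthalenediamine and 2,3-benzofuran both raised 61 genes (4.97 for independent lists), and 1,5-naphthalenediamine and coumarin 62 (4.08). 2,3-Benzofuran and 1,2-dibromoethane shared 86 (10.0). The counts depended on single animals. Without 2,3-benzofuran animal 1-10 they were 35 with coumarin (1.46 for independent lists), 22 with 1,5-naphthalenediamine (0.467) and 28 with 1,2-dibromoethane (1.01), and without corn oil control 1-22 they were 58, 30 and 40. The count of 2,3-benzofuran with 1,2-dibromoethane was 43 without 1,2-dibromoethane animal 2-52 and 48 without 2-58. Without feed control 1-29 the counts for 1,5-naphthalenediamine were 37 with 2,3-benzofuran and 40 with coumarin.

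Malathion, a negative chemical, shared 14 raised genes with 1,5-naphthalenediamine (1.45 for independent lists), 16 with coumarin (4.40) and 16 with 2,3-benzofuran (5.36), Ces1g, Nqo1 and Gpx2 among them. With 1,5-naphthalenediamine the shared count was 9 without feed control 1-29 or 1,5-naphthalenediamine animal 1-2, 1-4 or 1-5, 8 without feed control 2-42, 6 without malathion animal 2-38 or 2-39 and 27 without 2-33. With coumarin it was 5 without feed control 2-42, 8 without 2-44 or 2-45, 2 without malathion animal 2-38 (1.77 for independent lists) and 3 without 2-39. With 2,3-benzofuran it was 8 without corn oil control 1-22, 4 without 2,3-benzofuran animal 1-10, 27 without 1-8, 6 without feed control 2-42, 10 without 2-45, 26 without malathion animal 2-33, 4 without 2-38 and 3 without 2-39.

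Other genes were called in opposite directions with malathion and these chemicals, 1 with 1,5-naphthalenediamine, 10 with coumarin and 7 with 2,3-benzofuran. With 1,5-naphthalenediamine the number was 0 without feed control 2-42, 2-43 or 2-44 or malathion animal 2-33. With coumarin it was 21 without malathion animal 2-33 (24 raised by both), 5 without 2-39 (3 raised by both), 6 without feed control 2-43 or coumarin animal 2-76, and 4 without 2-80. Without malathion animal 2-38 it was 7, with 2 raised by both. With 2,3-benzofuran it was 18 without 2,3-benzofuran animal 1-6 (17 raised by both), 13 without 1-8, 0 without 1-10, 15 without malathion animal 2-33, 4 without 2-38 and 2 without 2-39. It was 3 without corn oil control 1-22 or feed control 2-43, and 4 without corn oil control 1-25 or feed control 2-42. The call of Nqo1 in malathion (1.25 ± 0.26, adjusted p = 0.00456) ended without malathion animal 2-38 (adjusted p = 0.0558).

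**Figure D3:**
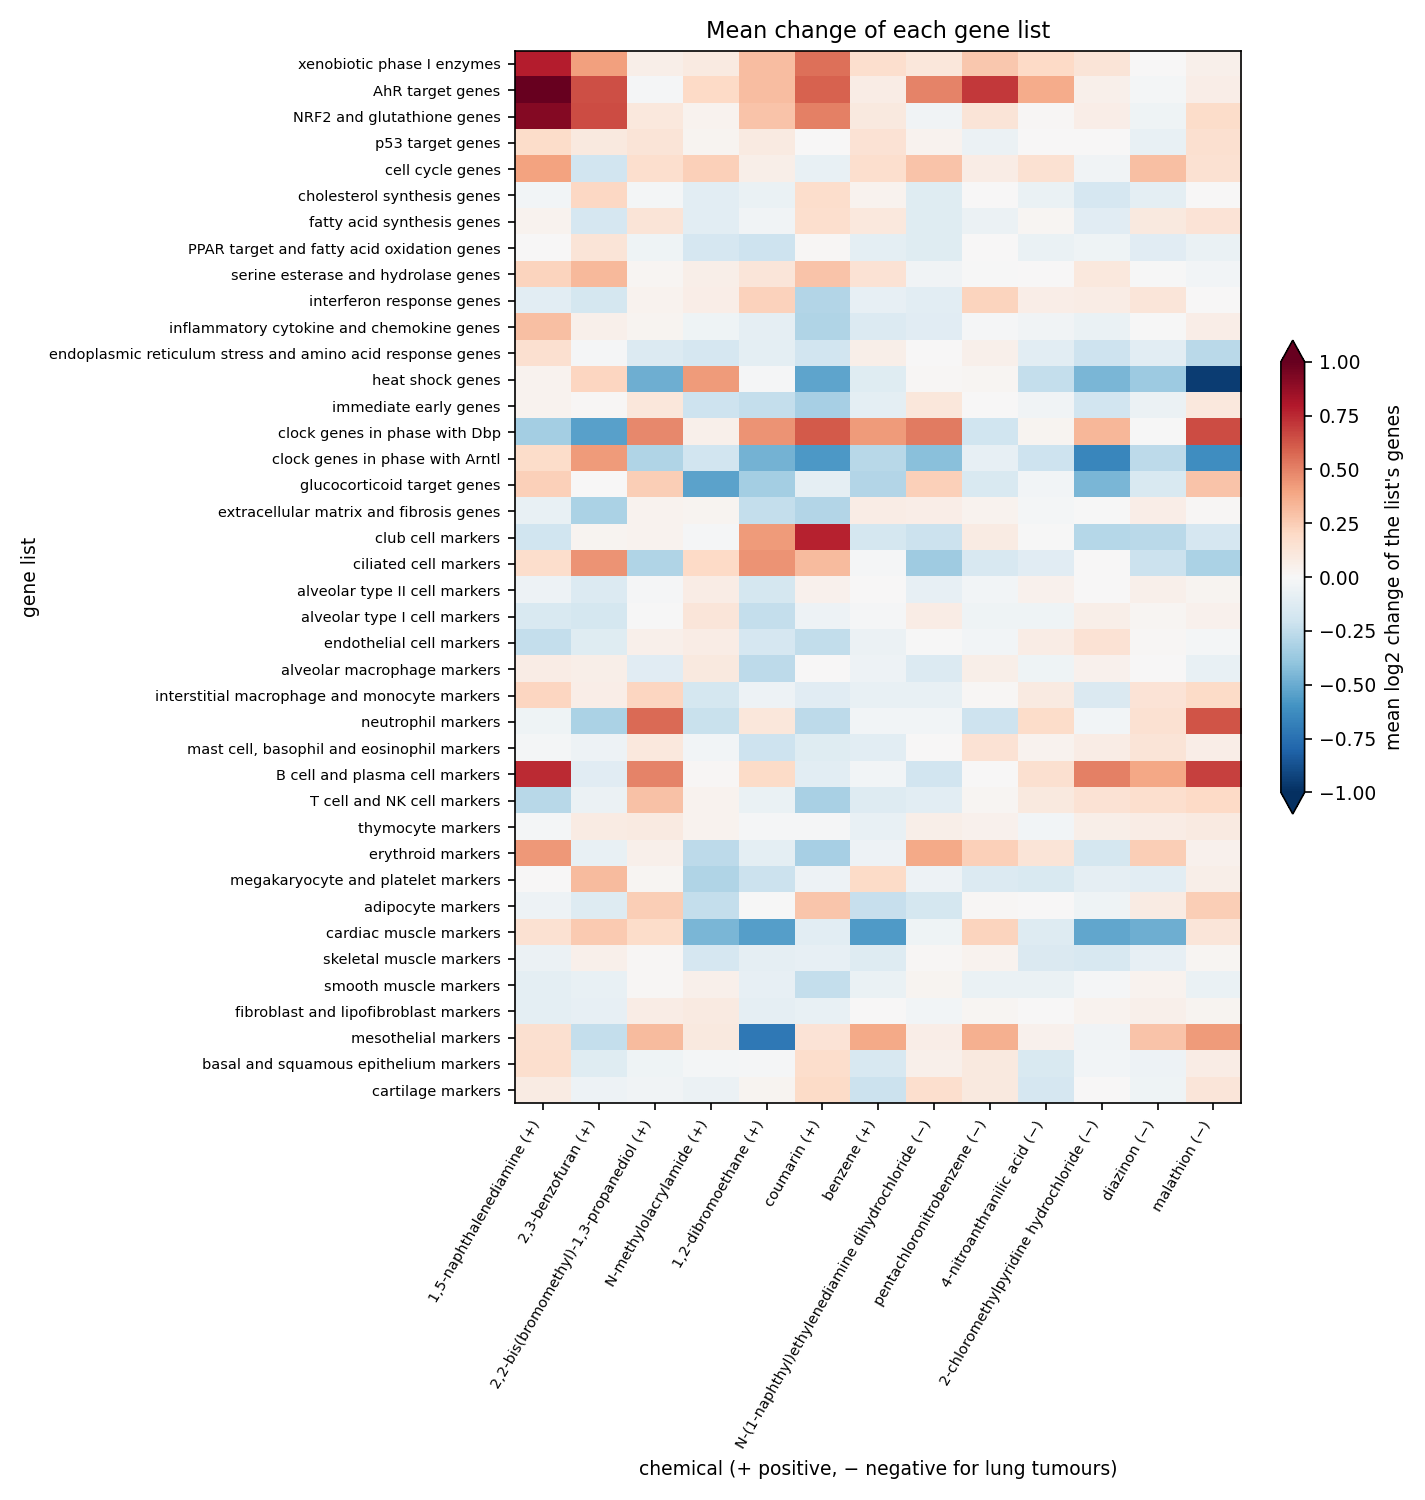
Mean log2 change of each of 40 gene lists (vertical) with each of 13 chemicals (horizontal), as colour on a scale that ends at -1 and 1. The AhR target genes reached 1.86 and the NRF2 and glutathione genes 0.92 with 1,5-naphthalenediamine, and the heat shock genes -0.95 with malathion.

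Of 520 pairs of a list and a chemical, camera with its preset correlation called 179, and 7 of these with an estimated correlation. The 7 were the AhR target genes with 1,5-naphthalenediamine and with pentachloronitrobenzene, the phase I enzymes with 1,5-naphthalenediamine and coumarin, and the NRF2 and glutathione genes with 1,5-naphthalenediamine, 2,3-benzofuran and coumarin. Without genes that another list holds, at the preset correlation, the call of the phase I enzymes ended with 1,5-naphthalenediamine (adjusted p = 0.185) and held with coumarin (0.0022), and the 3 calls of the NRF2 and glutathione genes held. The AhR target genes were then too few to test.

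The series title names the prediction of lung tumours as the aim, and the positive chemicals were compared with the negative ones with the chemical as the replicate (7 against 6). Limma called 0 genes (943 at an unadjusted p under 0.05, 729.65 expected by chance, smallest adjusted p 0.746). Of the genes with the smallest p, which did not pass, Hoatz, a ciliary gene, was higher with positive chemicals by 0.67 ± 0.15 and Rarb, a retinoic acid receptor, by 0.67 ± 0.16. Cd207, a marker of Langerhans-type dendritic cells, was lower (-0.37 ± 0.10), as was the Notch ligand Dll4 (-0.38). For Hoatz, 6 of 7 positive chemicals lay above all 6 negative ones, and 2,2-bis(bromomethyl)-1,3-propanediol lay at -0.21. The ciliated cell markers had a mean of 0.18 with positive and -0.19 with negative chemicals, 14 of 25 passing when adjusted over the list alone (camera adjusted p = 5.42e-17, and 0.251 with an estimated correlation). Club cell markers were also called higher (difference 0.27). Markers of endothelium (-0.13), T and NK cells (-0.16), alveolar type I cells (-0.09) and mast cells, basophils and eosinophils (-0.14, 3 of 6 passing over the list alone) and matrix genes (-0.14) were called lower. For these lists camera adjusted p ran from 3.45e-08 to 0.00252, and from 0.247 to 0.461 with an estimated correlation. The NRF2 and glutathione genes differed by 0.32 on average, with 1 member passing when adjusted over the list alone (camera adjusted p = 1.02e-14, and 0.444 with an estimated correlation). Without 2,2-bis(bromomethyl)-1,3-propanediol 4 genes passed. All 4 corn oil chemicals are positive, so that vehicle and tumour class overlap, and chemicals with the same controls are not independent of each other.

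With each chemical left out in turn and classed from 50 genes chosen on the other 12, 9 of 13 were classed correctly. These were 4 of 7 positive and 5 of 6 negative chemicals, the latter all given in feed. With permuted classes 19 of 100 permutations gave as many (permutation p = 0.198, one-sided), and the mean was 6.02. Without subtraction of the controls 5 of 13 were classed correctly. Benzene, N-methylolacrylamide and 2,2-bis(bromomethyl)-1,3-propanediol were called negative and 2-chloromethylpyridine hydrochloride positive. The genes chosen in every round were Acsm1, Agr3, Cxcl17, Erich2, Hoatz, Meig1, Rarb, Riiad1 and 1700016K19Rik.

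Control groups differed from each other by vehicle and by set. In set 2, Cyp2c29 and Cyp3a11, monooxygenases abundant in liver, were lower in the corn oil controls than in the feed controls (-3.73 ± 0.49, adjusted p = 3.07e-06, and -3.84 ± 0.75). Cyp2c29 (-3.87 ± 0.57) and Cyp3a11 (-4.40 ± 0.87) were also lower in the water than in the feed controls. The mean of 13 hepatocyte markers, Cyp3a11 among them, was 8.05, 6.88 and 6.76 in feed, corn oil and water controls. Liver tissue thus stays open as a source. Lbh, a transcriptional regulator, was higher in the corn oil than in the feed controls (1.32 ± 0.18, adjusted p = 3.07e-06). Acbd5, a peroxisomal acyl-CoA binding protein, was higher in the corn oil than in the water controls (1.68 ± 0.28, adjusted p = 6.11e-05). Between corn oil and feed controls 505 genes differed (244 higher, 261 lower), between corn oil and water controls 3340 (1789 higher, 1551 lower), and between water and feed controls 4924 (2264 higher, 2660 lower). Between corn oil and feed controls the count was 165 without feed control 2-42, 253 without 2-44, 201 without 2-45 and 828 without corn oil control 2-99. Between corn oil and water controls it was 2048 without water control 2-121, 1032 without 2-124, 5087 without corn oil control 2-132 and 1975 without 2-99, and between water and feed controls 3066 without water control 2-124 and 3067 without feed control 2-42.

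The same vehicle gave different levels in set 1 and set 2. Alb, serum albumin, was lower in the feed controls of set 1 than in those of set 2 (5.39 against 9.96, a difference of -4.57 ± 0.92), and so were Cyp3a11 (-5.06 ± 0.94), Serpina1b, a serum protease inhibitor (-4.39 ± 0.94) and Cyp2c29 (3.78 against 8.13). Alb was also lower in the corn oil controls of set 1 (-3.29 ± 0.82), whereas Aspn, a matrix proteoglycan, was higher there by 3.13 ± 0.32. Zfp62, a zinc finger gene, was higher in set 1 in both vehicles, by 3.28 ± 0.31 in feed and 3.07 ± 0.28 in corn oil. In all 6052 genes differed between the feed controls (1842 higher and 4210 lower in set 1) and 8102 between the corn oil controls (2765 higher and 5337 lower). Set cannot be told apart from whatever else differed between the sets, and no main comparison of a chemical with its controls crosses it. The alternative with controls of both sets pooled does.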

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

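The tests of the axis of variation in N-methylolacrylamide, of the feed controls in malathion and of the T cell and NK cell markers in 1,5-naphthalenediamine were chosen after the result was seen.

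In groups of at least 4 animals, single samples far from the others of their group were sought in the array measures and in the 4 genes with the largest change per chemical. Of 61 such tests 7 found one, where chance gives about 3.05 (1 in 20). The 3' minus 5' value was 0.989 in 1,2-dibromoethane animal 2-56 (others 0.135 to 0.254) and 0.345 in malathion animal 2-39 (others 0.192 to 0.216). It was 0.339 in corn oil control 2-99 of set 2 (others 0.159 to 0.240) and 0.238 in 4-nitroanthranilic acid animal 2-13 (others 0.162 to 0.172). The score on the first principal component was 1.22 in 2-chloromethylpyridine hydrochloride animal 2-119 (others 34.0 to 37.3). Phlda3 stood at 9.71 in benzene animal 2-90 (others 9.19 to 9.27), and Ces1g at 6.46 in corn oil control 2-59 (others 5.09 to 5.73). The groups of set 1, with 3 animals each, were too small for this test. There 2,3-benzofuran animal 1-10 had a 3' minus 5' value of 0.523 (others 0.161 and 0.102). Its score on the first principal component was -30.5 (others -51.3 and -47.6).

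Probe sets with no gene symbol or several were outside the comparisons, and some of the 5188 above the filter changed at an adjusted p under 0.05 in limma. They were 39 with 1,5-naphthalenediamine (37 higher, 2 lower), 184 with 2,3-benzofuran (44 higher, 140 lower) and 156 with N-methylolacrylamide (98 higher, 58 lower). There were 37 with 1,2-dibromoethane (24 higher, 13 lower), 42 with coumarin (27 higher, 15 lower), 24 with malathion (16 higher, 8 lower) and 1 with 2-chloromethylpyridine hydrochloride (lower).

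N-Methylolacrylamide animals differed from the water controls in 2605 genes, but from the feed controls of the same set in 127 and from the corn oil controls in 4. The count against the water controls fell to 299 without water control 2-124. Across genes, which are not independent replicates, the log2 changes correlated at -0.837 with the axis along which animals of the other groups differ within their group. 2-Chloromethylpyridine hydrochloride, also given in water, differed from the water controls in 0 genes, but from the feed controls in 2484 and from the corn oil controls in 135. Feed and corn oil controls had another vehicle, so that vehicle and chemical cannot be told apart in comparisons with them. Water controls that stand apart from the other controls may account for most of the genes called, and whether water gavage, handling or the arrays set them apart was not tested. An effect of N-methylolacrylamide itself stays open.

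Heat shock genes fell with malathion by a mean of 0.949 on the log2 scale. With any 1 of the 8 animals left out the mean change lay between -1.05 and -0.864, and all 9 members called lower stayed called with the 3' minus 5' value as a covariate, which argues against a single animal and against RNA integrity as the whole cause. The list also lay lower with the 3 other chemicals set against the same feed controls, by a mean change of -0.364, with -0.489 for 2,2-bis(bromomethyl)-1,3-propanediol, -0.365 for diazinon and -0.238 for 4-nitroanthranilic acid. Against other controls it was called lower with coumarin (-0.524) and 2-chloromethylpyridine hydrochloride (-0.460), and higher with N-methylolacrylamide (0.429). Part of the fall may lie in the feed controls, which the 4 groups share, and against them that part and an effect of malathion cannot be told apart. The list mean was 9.53 (SD 0.24) with malathion, 10.1 (SD 0.43) with diazinon, 10.2 (SD 0.18) with 4-nitroanthranilic acid and 9.99 (SD 0.26) with 2,2-bis(bromomethyl)-1,3-propanediol. That difference between treated groups does not rest on the controls, though single animals overlapped. The endoplasmic reticulum stress genes were also called lower with the 3 other chemicals (mean changes from -0.10 to -0.14), so that the limit of shared controls holds for them too.

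Immunoglobulin genes rose with 1,5-naphthalenediamine by a mean of 3.58 log2 units over Ighm, Jchain, Igk and Igkv6-14. The smallest mean with 1 animal left out was 3.23, without feed control 1-29, which argues against a single animal. The calls of Ighm and Jchain ended without that control, however. Lymphoid tissue caught with the lung would bring T cells, but the median change of 26 T cell and NK cell markers was -0.273 (quartiles -0.448 and -0.030), with 5 of them above 0. Whether the treated lungs held more antibody-secreting cells was not tested.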

How the results depend on the processing

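Chosen after the data were seen were the fits with a covariate, the fit without arrays that stand apart and the counts of genes shared between chemicals with each array left out. The cause of each change below was not tested, except that fits with fewer arrays have less to estimate the spread from. With the mean over all probe sets of a gene no count moved by more than 1.5 times. Without a filter 1 gene was called for 2,2-bis(bromomethyl)-1,3-propanediol (0 before), 2 for N-(1-naphthyl)ethylenediamine dihydrochloride (1) and 3 for diazinon (1). For diazinon 0 were called with a filter at the 50th percentile, with trend and robust estimation, with the 3' minus 5' covariate and with the amount handed to the core as a block. Quantile normalization over again gave 8 for benzene (13).

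Which direction held more genes changed with the processing in several comparisons, given here as higher and lower. For N-methylolacrylamide (1564 and 1041) array weights gave 2378 and 3592, and leaving out water control 2-129 gave 1939 and 2040. For 1,2-dibromoethane (283 and 305) the numbers were 317 and 211 with quantile normalization over again, 290 and 283 without a filter, 8 and 2 with only the arrays of the 2 groups, 347 and 102 with pooled controls and 466 and 361 with the axis covariate. They also turned without corn oil control 2-132 (250 and 243), 2-93 (245 and 209), 2-95 (266 and 244), 2-97 (244 and 181) or 2-99 (364 and 353). For malathion (151 and 169) the mean over probe sets gave 135 and 129 and pooled controls 2831 and 2071. Pooled controls also gave 291 and 1074 for 1,5-naphthalenediamine (140 and 22), 193 and 1444 for N-(1-naphthyl)ethylenediamine dihydrochloride (1 and 0) and 113 and 902 for pentachloronitrobenzene (1 and 0). For N-(1-naphthyl)ethylenediamine dihydrochloride array weights gave 312 and 396, only the arrays of the 2 groups 1 and 3, and no filter 1 and 1. Diazinon against malathion (16 and 25) gave 22 and 22 with quantile normalization.

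The balance between control groups of set 2 turned as well. Quantile normalization gave 2682 and 2547 for water against feed (2264 and 2660), 311 and 243 for corn oil against feed (244 and 261) and 1789 and 1839 for corn oil against water (1789 and 1551). The mean over probe sets gave 2731 and 2452, 283 and 245, and 1615 and 1806 in the same order. Array weights gave 4172 and 3412 for water against feed and 2358 and 2625 for corn oil against water. For corn oil against feed the numbers were 17 and 3 with only the arrays of the 2 groups and 245 and 227 with the 3' minus 5' covariate. They were 202 and 155 without feed control 2-43, 152 and 101 without 2-44, 106 and 95 without 2-45, 229 and 171 without corn oil control 2-134 and 309 and 241 without 2-60. Corn oil against water gave 2337 and 2750 without corn oil control 2-132 and 2053 and 2217 without water control 2-129, and water against feed gave 2777 and 2777 without the latter.

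With only the arrays of the 2 groups compared, the count was 293 for 1,5-naphthalenediamine (162), 9 for 2,3-benzofuran (594), 88 for 2,2-bis(bromomethyl)-1,3-propanediol (0), 1338 for N-methylolacrylamide (2605), 10 for 1,2-dibromoethane (588), 146 for coumarin (597), 0 for benzene (13), 4 for N-(1-naphthyl)ethylenediamine dihydrochloride (1) and 0 for diazinon (1). It was 486 for 1,5-naphthalenediamine against N-(1-naphthyl)ethylenediamine dihydrochloride (243), 0 for diazinon against malathion (41), 0 for corn oil against water controls (3340) and 20 for corn oil against feed controls (505). Array weights gave 910 for 1,5-naphthalenediamine, 1325 for 2,3-benzofuran, 2958 for 2,2-bis(bromomethyl)-1,3-propanediol, 5970 for N-methylolacrylamide, 1064 for coumarin, 212 for benzene, 708 for N-(1-naphthyl)ethylenediamine dihydrochloride, 75 for pentachloronitrobenzene, 313 for 4-nitroanthranilic acid, 314 for 2-chloromethylpyridine hydrochloride, 273 for diazinon and 2371 for malathion. They gave 1922 and 285 for the contrasts of 1,5-naphthalenediamine with N-(1-naphthyl)ethylenediamine dihydrochloride and of diazinon with malathion, 2307 for corn oil against feed controls and 7584 for water against feed controls.

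Controls of both sets pooled gave 1365 for 1,5-naphthalenediamine, 3866 for 2,3-benzofuran, 4049 for 2,2-bis(bromomethyl)-1,3-propanediol, 1214 for coumarin, 1637 for N-(1-naphthyl)ethylenediamine dihydrochloride, 1015 for pentachloronitrobenzene, 3 for 4-nitroanthranilic acid, 2123 for diazinon and 4902 for malathion. They turned Elovl6 in 2,3-benzofuran from -1.08 to 0.0342 and Mki67 in 2,3-benzofuran from -1.04 to 1.00. The amount handed to the core as a block gave 3 for 2,2-bis(bromomethyl)-1,3-propanediol and 178 for malathion (320). The 3' minus 5' covariate gave 1 for 4-nitroanthranilic acid (0). The covariate for the axis of variation gave 1040 for 2,3-benzofuran, 1 for N-methylolacrylamide, 1209 for coumarin, 1 for 4-nitroanthranilic acid, 2 for diazinon, 210 for malathion, 420 and 69 for the contrasts of treated groups, 143 for corn oil against water, 919 for corn oil against feed and 36 for water against feed controls, 1527 for the corn oil and 1932 for the feed controls of both sets (8102 and 6052). It turned Car3 between the corn oil controls of both sets from 3.36 to -0.28. Without corn oil control 2-132, whose mean deviation of 0.317 passed the limit of 0.298, corn oil against water controls gave 5087 (3340).

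With 1 array left out the counts ran from 80 to 130 for 1,5-naphthalenediamine, 47 to 1331 for 2,3-benzofuran, 0 to 8 for 2,2-bis(bromomethyl)-1,3-propanediol, 299 to 3979 for N-methylolacrylamide, 351 to 750 for 1,2-dibromoethane, 450 to 678 for coumarin, 5 to 13 for benzene, 1 to 9 for N-(1-naphthyl)ethylenediamine dihydrochloride, 1 to 1 for pentachloronitrobenzene, 0 to 0 for 4-nitroanthranilic acid, 0 to 1 for 2-chloromethylpyridine hydrochloride, 0 to 2 for diazinon and 77 to 299 for malathion. They ran from 158 to 226 for 1,5-naphthalenediamine against N-(1-naphthyl)ethylenediamine dihydrochloride, 6 to 142 for diazinon against malathion, 1032 to 5087 for corn oil against water, 165 to 828 for corn oil against feed, 3066 to 5554 for water against feed, 6715 to 8525 for the corn oil and 4584 to 6465 for the feed controls of both sets. With 1 chemical left out, tumour class called 0 to 4 genes, and 620 with animals as independent samples. The classifier without subtraction of controls was right for 5 chemicals (9). Of 179 calls of lists 7 held with an estimated correlation, and fry called 42. Without genes that another list holds, 172 of the 179 calls could be tested again, of which 149 held and 23 ended. The other 7 were all those of the AhR target genes, of which fewer than 5 members were left. Among the 23 were the phase I enzymes with 1,5-naphthalenediamine and the serine esterase and hydrolase genes with coumarin.

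A gene named in several comparisons is counted once for each. Of 358 pairs of a named gene and a comparison, 180 kept their direction and their call with each array left out, 185 with only the arrays of the 2 groups, 324 with array weights, 340 with the 3' minus 5' covariate and 300 with the covariate for the axis. Of 368 pairs, 355 did so without a filter, 351 with quantile normalization, 338 with the mean over probe sets and 364 with trend and robust estimation. The 368 include the 10 genes named for tumour class, which had no call to keep and counted as kept where they stayed uncalled. The other alternatives covered fewer pairs: 328 of 328 did so with a filter at the 50th percentile, 31 of 39 with the amount handed to the core as a block, 182 of 231 with controls of both sets pooled (2 reversed) and 136 of 156 without arrays that stand apart. No paired analysis was possible because the animal identifiers share no replicate numbers between groups. Signal over background was not given in the sources used here, and a gene below the filter was not tested.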

Other observations

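The tests of the body clock and of liver tissue in this part were chosen after the result was seen.

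Lists of lung cell markers were called in both directions with 1,2-dibromoethane at the preset correlation, and 0 of them with an estimated one. Of 22 alveolar macrophage markers 4 fell and 6 when adjusted over the list alone, with Siglecf the largest (-1.07 ± 0.21; camera adjusted p = 0.000128, and 0.465 with an estimated correlation). Of 15 alveolar type I cell markers 4 fell and 6 when adjusted over the list alone, with a mean change of -0.24 (camera adjusted p = 1.34e-05, and 0.344 with an estimated correlation). Of 20 endothelial markers 2 fell and 6 when adjusted over the list alone, Tmem100 by -0.38 ± 0.09 and Car4, a carbonic anhydrase of lung capillaries, by -0.47 ± 0.10 (camera adjusted p = 0.000325, and 0.344 with an estimated correlation). Of 19 alveolar type II cell markers 6 fell, and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000132, and 0.4 with an estimated correlation). Of 11 mesothelial markers 2 fell and 4 when adjusted over the list alone (camera adjusted p = 0.000375, and 0.584 with an estimated correlation). Club cell markers went the other way: 4 of 14 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000113, and 0.4 with an estimated correlation). Markers of B cells (higher) and of platelets, cardiac muscle and fibroblasts (lower) were also called, with 0 to 2 members passing (camera adjusted p from 0.00442 to 0.0449, and from 0.53 to 0.839 with an estimated correlation).

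With the 3' minus 5' value as a covariate 442 of the 588 genes called for 1,2-dibromoethane stayed called. Siglecf in 1,2-dibromoethane (-1.01, adjusted p = 0.00509), Tmem100 in 1,2-dibromoethane (-0.45, adjusted p = 0.00121) and Car4 in 1,2-dibromoethane (-0.48, adjusted p = 0.0077) were among these, and the lists were not tested with the covariate.

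Cell markers moved in both directions with malathion. Of 14 club cell markers 3 fell, and 5 when adjusted over the list alone, Cyp2f2, the main monooxygenase of these cells, by -0.32 ± 0.06 (adjusted p = 0.00156; camera adjusted p = 9.76e-05, and 0.4 with an estimated correlation). Of 25 ciliated cell markers 1 fell and 3 when adjusted over the list alone (camera adjusted p = 3.4e-05, and 0.613 with an estimated correlation). Of 20 B cell and plasma cell markers 1 rose and 11 when adjusted over the list alone, with a mean change of 0.69 (camera adjusted p = 3.36e-07, and 0.359 with an estimated correlation). Of 26 T cell and NK cell markers 5 rose, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00674, and 0.783 with an estimated correlation). Neutrophil markers (0 members passing, also 0 when adjusted over the list alone) and mesothelial markers (1, also 1) were called higher too (camera adjusted p = 0.00239 and 0.0409, and 0.763 and 0.834 with an estimated correlation). The B cell, T and NK cell and ciliated lists were called in the same directions with the other chemicals set against these feed controls. In that order the mean changes were 0.50, 0.30 and -0.30 with 2,2-bis(bromomethyl)-1,3-propanediol, 0.39, 0.17 and -0.22 with diazinon, and 0.16, 0.10 and -0.11 with 4-nitroanthranilic acid. For these lists a part in the shared controls and an effect of malathion or diazinon cannot be told apart.

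With 1,5-naphthalenediamine 3 of 26 endoplasmic reticulum stress genes rose, and 6 when adjusted over the list alone, led by Edem1 (1.03 ± 0.15, adjusted p = 2.2e-06; camera adjusted p = 0.00241, and 0.499 with an estimated correlation).

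Body clock genes moved in opposition between groups. Over the 12 groups of set 2, the mean of clock genes in phase with Dbp and the mean of those in phase with Arntl had r = -0.747 (permutation p = 0.00702, Benjamini-Hochberg 0.0187 over 9 relations; rho = -0.762, permutation p = 0.00593), and -0.646 without the 2 groups farthest from the median. Over the 6 groups of set 1 r was -0.945 (exact permutation p = 0.00833, adjusted 0.0187; rho = -0.829, exact permutation p = 0.0583), and -0.566 without the 2 farthest, so that it rests on those. For the deviations of the 52 animals of set 2 from their group means r was -0.684 (permutation p = 1e-05, the smallest that the permutations can give; adjusted 4.5e-05; rho = -0.662).

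The heat shock genes may follow the phase of the clock at sampling. The difference between both clock lists ran from 0.867 in the corn oil controls to 2.15 with malathion in set 2, and the heat shock list mean from 10.5 in the feed controls to 9.49 with 2-chloromethylpyridine hydrochloride and 9.53 with malathion. Over the 11 groups of set 2 other than malathion r was -0.605 (permutation p = 0.0459, adjusted 0.0826; rho = -0.609, permutation p = 0.0526), and -0.156 without the 2 farthest groups, so that the relation rests on those, and the 6 groups of set 1 gave -0.327 (exact permutation p = 0.608). The bound of -0.6 was set after the group values were seen, and the demand that it also hold without 2 groups after the result was known. For deviations of 52 animals from their group means r was -0.567 (permutation p = 1e-05, the smallest that the permutations can give; adjusted 4.5e-05; rho = -0.60), and -0.506 without the 2 farthest. The time of day at sampling is not given in the sources used here, and sampling time and chemical cannot be told apart for the groups. Cirbp gave r = 0.489 with the clock difference over the 11 groups (permutation p = 0.127, adjusted 0.19; rho = 0.418) and 0.0206 over the 52 deviations (permutation p = 0.883, adjusted 0.883; rho = 0.0786).

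Liver transcripts differed between control groups, and Cyp2c29 fell with diazinon and malathion, so that liver tissue in the feed controls of set 2 was tested as a source. A list of 25 hepatocyte markers without Cyp2c29 was written for the test, of which 23 were measured and 13 lay above 6 log2 units in these controls, such as Alb (9.96), Rbp4 (9.78) and Fabp1 (9.69), and lung cells express some of them, Rbp4 and Cyp2e1 among them. With malathion their median change was 0.306 (quartiles 0.113 and 0.657; 3 of 13 lower), while Cyp2c29 fell by 2.62, which argues against liver tissue as the source of that fall. With diazinon the median was -0.289 (quartiles -0.512 and -0.061; 10 of 13 lower) against a fall of 2.98 for Cyp2c29, and a part from liver tissue cannot be told apart there, because the groups are small and the markers moved unevenly. Cyp3a11 did not pass in diazinon (-2.95, limma adjusted p = 0.883) or in malathion (-2.33, adjusted p = 0.135). Over all groups Alb ran from 5.29 in the corn oil controls of set 1 to 10.3 with 4-nitroanthranilic acid. Cyp2c29 was highest in the feed controls of set 2 (8.13, SD 0.81) and ran from 3.78 to 7.29 in the other groups. Against these controls it also lay lower, without a call, with 2,2-bis(bromomethyl)-1,3-propanediol (5.65, SD 1.23) and 4-nitroanthranilic acid (7.29, SD 1.03). High values in these controls and an effect of diazinon or malathion therefore cannot be told apart.

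The difference between corn oil and feed controls was set against the same difference in the other set. Limma called 0 genes for this interaction, with a smallest adjusted p of 0.094 for Cyp2c29 (0.20 in set 1 and -3.73 in set 2), Lbh (-0.07 and 1.32) and Cap2 (0.20 and -0.77).

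Other splits of the same arrays into groups of the same sizes were counted for each result. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05: 1 of 10 gave as many genes for 1,5-naphthalenediamine (162, highest other 1), 1 for 2,3-benzofuran (594, highest other 106), 2 for N-(1-naphthyl)ethylenediamine dihydrochloride (1, highest other 2), 2 for pentachloronitrobenzene (1, highest other 2) and 1 for the direct contrast of 1,5-naphthalenediamine with N-(1-naphthyl)ethylenediamine dihydrochloride (243, highest other 2). The share lay under 0.05 for malathion (1 of 35 splits: 320, highest other 68) and for water against feed controls (1 of 35: 4924, highest other 3505). It also did for feed controls of set 1 against set 2 (1 of 35: 6052, highest other 5733) and for the corn oil controls of both sets (1 of 100: 8102, highest other 6359). These are the smallest shares that the splits can give, and they were not adjusted over the results split, so that chance is not excluded.

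Chance was not excluded for the results that follow. As many genes came from 2 of 35 splits for N-methylolacrylamide (2605, highest other 2803), from 2 of 35 for diazinon against malathion (41, highest other 100) and from 6 of 35 for diazinon (1, highest other 2). Of 100 splits drawn, 12 gave as many for 1,2-dibromoethane (588, highest other 2472), 15 for coumarin (597, highest other 3114), 23 for benzene (13, highest other 3529), 7 for corn oil against water controls (3340, highest other 5044) and 7 for corn oil against feed controls (505, highest other 1802). The splits that called many more genes than the real groups, such as 3529 for benzene, 3114 for coumarin and 2472 for 1,2-dibromoethane, point to a structure among the arrays of set 2 that the groups do not follow. The count of genes is the measure here, and the largest single changes, such as that of Ces1g with coumarin, were not set against the splits.

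Where 0 genes were called, every split gives as many, so that the splits say nothing about chance. This holds for 35 of 35 splits for 2,2-bis(bromomethyl)-1,3-propanediol (0, highest other 5), 4-nitroanthranilic acid (0, highest other 1) and 2-chloromethylpyridine hydrochloride (0, highest other 1), and for all 100 splits of the 13 chemicals for the tumour classes (0, highest other 19).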
